A study of Homo sapiens with 45 samples.

How the data were processed

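ChIP-seq libraries of HEK293 cells were made from nuclei treated with micrococcal nuclease and sonication, with the ThruPLEX kit, and sequenced on a HiSeq 4000, per the labels' protocols. The series lists 45 samples. A region list was used for 39 of them, and 6 input samples were used only through the input values inside those lists. Groups, antibodies and replicate numbers were taken from the labels. The labels do not say whether replicates are separate cultures, so p-values measure the spread between these samples, which may be technical.

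Per the submitters' processing notes the tools were CASAVA 1.4, BWA 0.5.9, SICER 0.1.1 and MACS2 2.0.10 on the hg19 build. The 34 island lists were called by SICER per library against an input, with a window of 200 bp, a gap of 600 bp and a false discovery rate of at most 0.01, per the labels on the deposited lists. They hold, per the file headers, 4 kinds of value: the raw count of ChIP reads and the count of input reads in each island, a fold ratio of ChIP over input, a p-value and its adjusted form. The fold ratio is scaled by 1 factor per deposited list, and its lowest value was 1.95 in every one, so the authors' lists had passed a fold filter. The 5 H3K4me3 lists were called by MACS2 per library with a q-value of at most 0.01, per the file headers. They hold, per the file headers, a pileup signal at the summit after the larger of ChIP and input was scaled to the smaller, a fold enrichment ratio, and the −log10 of the p-value and q-value. Replicates were not pooled in any list. The authors' fold and p-values were used only to filter or describe regions within a list.

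Islands of one antibody were merged across its 4 siRNA libraries wherever they overlapped by at least 1 bp. For the 6 antibodies on islands, ChIP read counts were summed over each region called in all 4 libraries and tested with the quasi-likelihood test of edgeR 4.0.16 (robust, TMM scaling, library size the reads in islands, condition as the only term, two-sided). Reads were counted only inside islands, and each library has its own island borders, so a count carries the length that was called as well as the occupancy. For H3K4me3, log2 of the highest pileup of each region was centred on each library's median and tested with limma 3.58.1 (trend, robust, two-sided), with no pseudocount because all 4 values were above 0. P-values were adjusted by Benjamini-Hochberg per antibody, with a threshold of 0.05. Tested regions were 46.3% of all merged RNAPII regions, 26.2% for S5p, 37% for S2p, 32.6% for SPT5, 59.9% for H3K36me3, 48.5% for H3K27me3 and 59% for H3K4me3. Chromosome 1 was left out for S5p, because siZC3H4 replicate 1 listed 0 islands there and the other 3 libraries 1093, 3086 and 3719.

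In untreated cells, ZC3H4 regions found in both replicates were compared with regions of WDR82, CK2a and SPT5 found in both replicates and with the single RNAPII, H3K4me3 and H3K27me3 lists. The overlap was set beside 1000 seeded random placements within the same chromosomes, with a one-sided permutation p in each direction. Gained regions were those called in both siZC3H4 and neither siCon library, and lost regions the reverse, and the other 2 ways of splitting the 4 libraries give the spread. ZC3H4-bound regions were compared with the rest by camera in limma, adjusted over the 7 antibodies. Contexts of called regions were compared with Fisher's exact test in SciPy 1.17.1, two-sided. Island widths at H3K4me3 peaks of both siCon replicates were compared by an exact permutation test on the library means. The width was that of the first overlapping island along the chromosome. A region broken into several islands was thus measured by 1 of them, and an island that spanned several peaks counted for each. Other tools were Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, Matplotlib 3.10.9 and R 4.3.3.

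The groups, main tests, alternatives and the rule for regions named in the text were fixed before the data were examined. That rule took, per antibody, regions past the threshold with a mean of at least 50 reads (no minimum for H3K4me3) and the same direction in both same-numbered pairs, up to 12 with the largest increase and 12 with the largest decrease, or, where fewer than 5 passed, the 10 with the smallest p. It also took the 15 ZC3H4 regions with the highest read density and, per antibody, the 5 gained and 5 lost regions with the most reads. The text gives the first of each list. Alternatives were DESeq2 1.42.0, other scalings, filters and overlaps, an offset for covered length, the replicate block and each library left out in turn. A scaling to whole-library depth, from each list's ChIP to input ratio and the input read density, was chosen after seeing the data. Fisher's exact tests of the contexts of called, gained and lost regions were not part of the plan either.

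The tests were tested on simulated data with 200 changed regions per antibody, drawn from the means, library sizes and spread of the real libraries. Of 2-fold changes, 83% were recovered for RNAPII, 32% for S5p, 12% for S2p, 60% for SPT5, 59% for H3K36me3, 27% for H3K27me3 and 100% for H3K4me3. Of 4-fold changes, 100%, 91%, 81%, 99%, 93%, 84% and 100% were recovered in the same order. Calls at regions simulated without a change numbered 23, 14, 21, 22, 25, 9 and 11, and 0 calls had the wrong direction. For every antibody these false calls made up a share of more than 0.05 of all simulated calls. The adjusted p threshold of 0.05 was therefore not fully held in this simulation. Overlap counting gave 0 mismatches in 10834 simulated comparisons. With the spread between these libraries, most simulated 2-fold changes of S5p, S2p and H3K27me3 were missed.

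Same-numbered replicates were checked for pairing by the correlation of their deviations from the condition means, which was 0.466 for RNAPII, 0.333 for S5p, 0.439 for H3K36me3, 0.185 for H3K27me3, 0.165 for H3K4me3, 0.085 for SPT5 and -0.205 for S2p. The deposited lists show that replicate 1 of RNAPII, and of S5p, came from 1 run in both conditions, and that the H3K36me3 replicate number matched the lane in both, so blocked values stand beside those results. The siCon and siZC3H4 libraries of every antibody were called against different inputs.

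The reference gene table given here is on GRCh38, and coordinates were not converted between builds. The comparison of upstream with downstream reach at annotated promoters and the tests of gene lists were therefore not run, and island width at H3K4me3 peaks was used in place of the first. Regions on a list of places that give signal with any antibody were not removed. Intervals and tests cover counting error and the spread between libraries only.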

Results

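Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in HEK293 cells, a human embryonic kidney line, to map ZC3H4 and to ask what its loss does to RNA polymerase II (RNAPII), the elongation factor SPT5 and histone marks. ZC3H4 is, per the labels, the scaffold of a complex with the adaptor WDR82 and the protein kinase CK2, and the series concerns SPT5 phosphorylation and divergent antisense transcription at active promoters. The deposited region lists covered 39 ChIP libraries. Of these, 11 came from untreated cells, 14 from cells given a control siRNA (siCon) and 14 from cells given an siRNA against ZC3H4 (siZC3H4). Untreated cells were profiled for ZC3H4, WDR82, CK2a and SPT5 in 2 replicates each, and for RNAPII, H3K4me3 and H3K27me3 in 1 library each. Both siRNA conditions were profiled in 2 replicates each for 7 antibodies, namely total RNAPII, RNAPII S5p (the form phosphorylated on serine 5, found mainly near promoters), RNAPII S2p (the form phosphorylated on serine 2, found mainly along elongating genes), SPT5, H3K4me3 (a promoter mark), H3K36me3 (a mark of transcribed gene bodies) and H3K27me3 (the Polycomb mark of silent chromatin). The 34 libraries with enriched islands held 6369 to 50148 islands each, and 0.284 to 5.924 M ChIP reads in islands in untreated cells, 2.472 to 22.137 M in siCon cells and 3.339 to 23.922 M in siZC3H4 cells. The 5 H3K4me3 libraries held 28352 to 35172 peaks. No ZC3H4 profile of siRNA-treated cells was analysed here, so the depletion itself was not measured. Regions are given by hg19 position, because no gene annotation of that build was used here.

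The first question was where ZC3H4 sits in untreated cells. ZC3H4 occupied 1393 regions in both replicates, which covered 7.09 Mb with a median width of 4400 bp, and most of these shared regions lay at RNAPII and H3K4me3. Of these regions, 92.8% overlapped an RNAPII island and 90.5% an H3K4me3 peak, whereas random placements gave means of 6.96% and 5.12%. SPT5 lay at 87.8% of them (random mean 5.55%), WDR82 at 73.9% (2.84%) and CK2a at 64.8% (2.28%). H3K27me3 lay at 1.87%, below the random mean of 13.1%. Random draws among the regions of any untreated library gave higher means, with 23.34% for RNAPII, 24.35% for H3K4me3, 17.43% for SPT5, 8.92% for WDR82, 7.24% for CK2a and 45.04% for H3K27me3. All 6 differences reached 0.0010 under both, the smallest one-sided permutation p that 1000 placements can give. Each ZC3H4 replicate shared its run and input with 1 WDR82 and 1 CK2a library, and replicate 1 also with RNAPII, which neither kind of random region models. The 2 ZC3H4 libraries shared little of their covered sequence (Jaccard index 0.049), and the overlaps were smaller for either alone: with replicate 1 (10237 islands) and replicate 2 (6369 islands) they were 66.05% and 37.93% for RNAPII, 56.97% and 35.78% for H3K4me3, 56.5% and 35.03% for SPT5, 39.99% and 25.2% for WDR82, and 29.83% and 23.46% for CK2a, each still at a permutation p of 0.0010. H3K27me3 lay at 0.8% of replicate 1 islands and, with replicate 2 alone, at 18.7%, above its random mean of 14.3%.

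**Figure D1:**
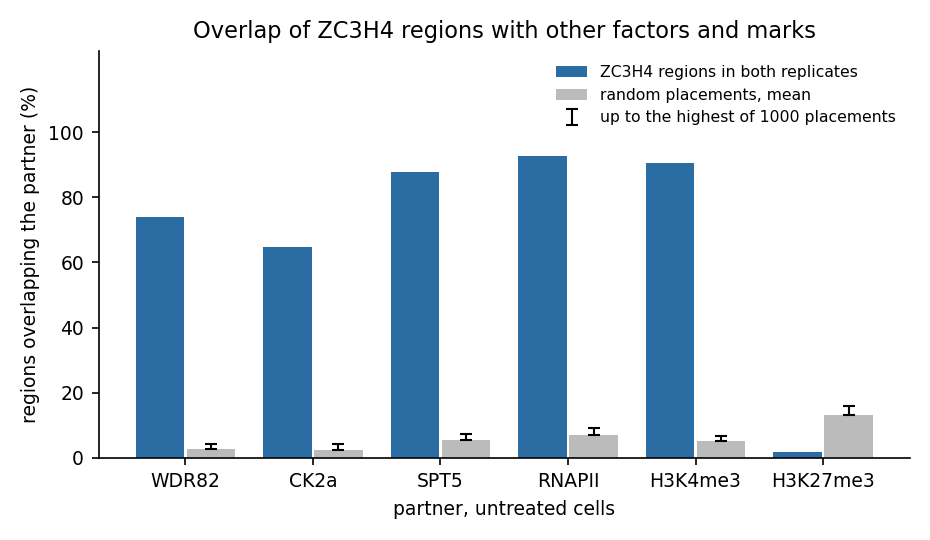
Percentage of the 1393 ZC3H4 regions of untreated cells that overlap each partner (blue bars, vertical axis in percent) beside the mean of 1000 random placements (grey bars), with error bars up to the highest placement. RNAPII overlaps 92.8% of the regions and H3K27me3 1.87%.

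Both partners of the complex accompanied ZC3H4 at 745 regions (53.5%), at least one of them at 1187 (85.2%) and neither at 206 (14.8%). The reverse overlap was smaller: 14.9% of WDR82 regions and 16.2% of CK2a regions held ZC3H4. ZC3H4 was found at 8.5% of RNAPII islands with an H3K4me3 peak and at 1.7% of those without, and the share was higher at denser islands, with 2.3% in the lowest 10% of RNAPII islands by read density and 17.4% in the highest 10%. RNAPII islands with ZC3H4 had a median of 67.8 RNAPII reads per kb against 44.2 in those without, and were also wider (median 5000 against 3400 bp), which raises the chance of any overlap. The regions with the highest ZC3H4 read density included chr21:9825601-9827400 (55.0 and 58.9 reads per kb in replicates 1 and 2), chrX:71400001-71402000 (40.6 and 43.5), chr9:135230001-135231400 (30.7 and 65.0), chr1:148241001-148242000 (36.2 and 40) and chr14:23388201-23389800 (31.9 and 43.3). Among the 15 densest regions, 15 overlapped RNAPII and H3K4me3, 13 SPT5, 12 WDR82, 11 CK2a and 1 H3K27me3, the last being the chromosome 21 region. Densities are not scaled for depth, and regions that give signal with any antibody were not removed.

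The second question was which regions changed in siZC3H4 cells, and H3K4me3 gave the most in the main tests. Its test differs from that of the islands and recovered more of the simulated 2-fold changes, though these were simulated with 1 spread for all regions. The numbers of calls are therefore not comparable between antibodies. Among 18298 H3K4me3 regions called in all 4 libraries, the peak pileup rose at 486 and fell at 940 (limma, adjusted p under 0.05), with median folds of 1.38 and 1.51. Few changes were large: 22 of the regions that rose and 62 of those that fell passed 2-fold. H3K4me3 rose most at chr2:74606571-74607463 (log2 change 1.49 ± 0.23 SE, limma adjusted p = 2.31e-05; pileup 21 and 23 in siCon, 48 and 84 in siZC3H4), followed by chr15:32904127-32905075 (1.46 ± 0.23, adjusted p = 3.01e-05) and the ZC3H4-bound chr17:7482996-7487051 (1.40 ± 0.19, adjusted p = 2.03e-06). It fell most at chr5:180594673-180596553 (-1.89 ± 0.23, limma adjusted p = 2.24e-07; pileup 72 and 79 against 23 and 19), chr16:73511494-73512225 (-1.68 ± 0.22, adjusted p = 9.94e-07) and chr7:149387315-149389147 (-1.66 ± 0.17, adjusted p = 1.4e-08). Both same-numbered pairs moved the same way at all 1426 regions. These regions were called from the same 4 libraries, so this largely follows from the call and is not separate evidence. The balance of higher to lower calls depended on the scaling and the measure: quantile normalization gave 744 higher and 732 lower and cyclic loess 776 and 783, while the sum of the pileups in a region gave 258 and 53 and the fold enrichment 1344 and 1655. With the replicate number as a block the counts were 881 and 1660, while leaving out 1 library gave 397 and 607 (without siCon replicate 1), 277 and 498 (without siCon replicate 2), 217 and 786 (without siZC3H4 replicate 1) and 284 and 395 (without siZC3H4 replicate 2).

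The H3K4me3 regions that rose and those that fell lay in different surroundings. An RNAPII island of siCon cells overlapped 86.6% of the regions that rose, 64.9% of those that fell and 80.2% of those that passed in neither direction (higher against lower, odds ratio 3.5, Fisher's exact test, adjusted p = 1.44e-18 over 8 region sets). SPT5 gave 81.3% and 65.6% for regions that rose and fell (adjusted p = 1.65e-09) and H3K36me3 40.5% and 25.1% (adjusted p = 8.76e-09, the same test). H3K27me3 went the other way, with 1.4% and 5.5% (adjusted p = 1.85e-04), as did WDR82 with 26.3% and 36.2% (adjusted p = 2.34e-04). ZC3H4 itself lay at 8.6% of the regions that rose and 7.6% of those that fell (adjusted p = 0.498). Neighbouring regions are not independent, so the p values of these Fisher tests are too small. Camera in limma compared the H3K4me3 change between tested regions with and without each set. Its adjusted p was 0.00118 for RNAPII, 0.0209 for SPT5, 0.153 for H3K36me3 and 0.0387 for H3K27me3 with a preset correlation between regions. With an estimated correlation none passed (0.296, 0.414, 0.671 and 0.663). Regions that fell had a lower median pileup (109) than those that rose (176.5) and those that passed in neither direction (220). They were also narrower (median 1623 bp against 2841 and 2986 bp), which lowers the chance of any overlap. With cyclic loess the RNAPII odds ratio was 2.19 (adjusted p = 1.60e-09) and the H3K27me3 difference no longer passed (2.6% against 4.1%, adjusted p = 0.137). With the sum of pileups the WDR82 difference turned and did not pass (52.7% of higher against 45.3% of lower regions, Fisher's exact test, adjusted p = 0.419), nor did H3K27me3 (0.8% against 0%, adjusted p = 1.00) or ZC3H4 pass (15.5% against 5.7%, adjusted p = 0.104), although ZC3H4 was more frequent in higher regions than in those that passed in neither direction (8.4%, Fisher's exact test, adjusted p = 2.02e-04).

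**Figure D2:**
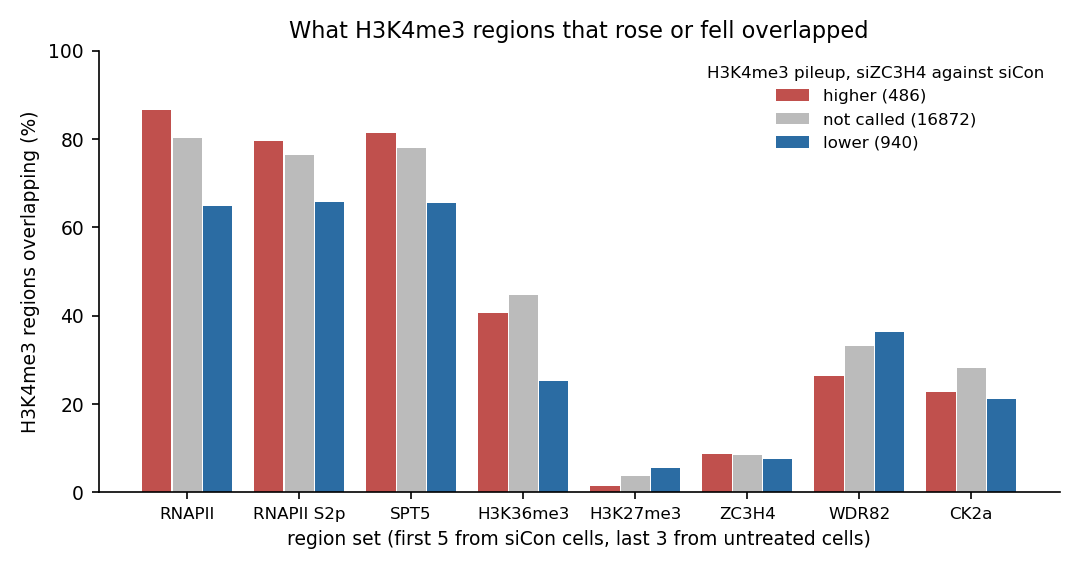
Percentage of H3K4me3 regions (vertical axis) that overlap each region set, for regions whose pileup rose (red, 486), fell (blue, 940) or passed in neither direction (grey, 16872) in siZC3H4 against siCon cells under median centring. RNAPII overlaps 86.6% of the regions that rose and 64.9% of those that fell.

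SPT5 had calls in edgeR without a replicate block, unlike the 3 RNAPII profiles. Among 11536 SPT5 regions called in all 4 libraries, island reads rose at 3 and fell at 10 (edgeR quasi-likelihood test, adjusted p under 0.05). SPT5 rose at chr7:82553801-82582400 (log2 change 3.08 ± 0.21 SE, edgeR adjusted p = 0.0145; 84 and 37 reads in siCon, 532 and 488 in siZC3H4), at chr6:97632601-97641600 (2.12 ± 0.23, adjusted p = 0.0369) and at chr7:90010801-90021800 (1.91 ± 0.19, adjusted p = 0.0334). It fell at chr10:27019601-27047800 (-2.50 ± 0.19, edgeR adjusted p = 0.0145; 845 and 369 reads against 118 and 95), chr15:89848601-89880000 (-2.26 ± 0.21, adjusted p = 0.0243), chr10:64913801-64937400 (-2.10 ± 0.17, adjusted p = 0.0179) and 7 more regions. Of the 13 regions, 12 overlapped H3K36me3 of siCon cells, 5 overlapped H3K4me3, and 0 overlapped a ZC3H4 region of both replicates but 6 an island of either replicate. Over all 11536 tested SPT5 regions the shares were 61.8% for H3K36me3, 92.0% for H3K4me3 and 10.4% for ZC3H4 of both replicates. An island of either ZC3H4 replicate lay at 5995 of them. With only 13 regions, 0 at ZC3H4 cannot be told from a share of 10.4%. Without siCon replicate 1 or 2, 0 regions passed in edgeR (851 and 718 at an unadjusted p under 0.05), without siZC3H4 replicate 1 there were 20 higher and 65 lower, without siZC3H4 replicate 2 there were 9 and 33, and DESeq2 called 27 and 58. The replicate block gave 17 higher and 45 lower, and regions called in at least 2 libraries gave 0 and 0 in edgeR (3746 at an unadjusted p under 0.05). With an offset for the length that islands covered in each library, 7 regions were higher and 0 lower and 11 of the 13 changed sign, and scaling to an estimate of whole-library depth, chosen after seeing the data, put the median of all SPT5 regions at -0.50 on the log2 scale and called 9 higher and 363 lower.

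**Figure D3:**
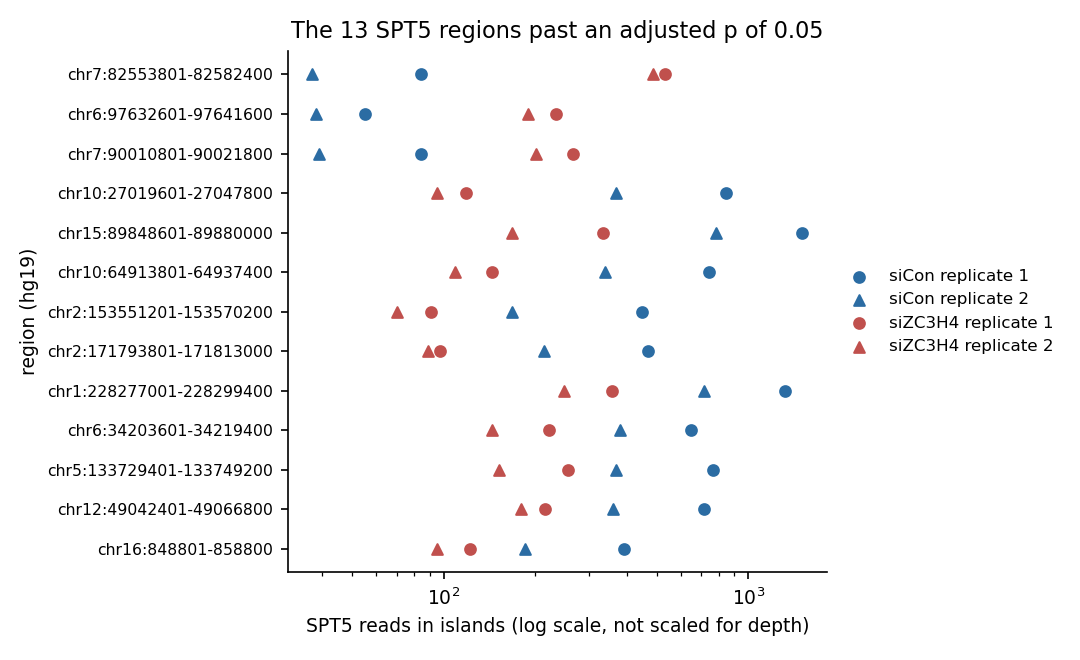
SPT5 reads in islands (horizontal log axis, not scaled for depth) in each siCon (blue) and siZC3H4 (red) library at the 13 regions past an adjusted p of 0.05, circles for replicate 1 and triangles for replicate 2. The first 3 regions have more reads in both siZC3H4 libraries and the other 10 fewer; an offset for covered length turned 11 of the 13.

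H3K27me3 rose at 2 of 19526 regions (edgeR, adjusted p under 0.05). Both were domains without RNAPII, H3K4me3 or ZC3H4: chrX:76206401-76270000 (log2 change 2.97 ± 0.09 SE, edgeR adjusted p = 0.00287; 494 and 338 reads in siCon, 2889 and 2741 in siZC3H4) and chr12:53056801-53101800 (2.40 ± 0.14, adjusted p = 0.0454; 441 and 250 against 1701 and 1412). None of the 19526 regions fell (1026 at an unadjusted p under 0.05), while DESeq2 called 16 higher and 18 lower. Without siZC3H4 replicate 1 or 2 no region passed in edgeR (1068 and 763 at an unadjusted p under 0.05), and without siCon replicate 1 or 2 there were 6 and 4 higher. With the covered-length offset neither of these 2 regions passed, and 1 other region was higher. Testing regions called in at least 2 libraries left 0 in edgeR (3112 at an unadjusted p under 0.05).

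Polymerase and H3K36me3 regions named here did not pass in edgeR and were taken by smallest p. Total RNAPII had its smallest p at chr19:11428401-11435600 (log2 difference -1.78 ± 0.16 SE, edgeR adjusted p = 0.262; 319 and 433 reads in siCon, 104 and 100 in siZC3H4), chr10:75552401-75576000 (1.19 ± 0.12, adjusted p = 0.272), the ZC3H4-bound chr22:42321201-42348000 (-1.07 ± 0.13, adjusted p = 0.374) and chr5:139117201-139120000 (1.22 ± 0.16, adjusted p = 0.582). Of 12078 RNAPII regions, 0 passed in edgeR (709 at an unadjusted p under 0.05), and DESeq2 called 5 higher and 4 lower. Replicate 1 of both conditions came from a sequencing run of its own, and with the replicate number as a block 13 regions were higher and 5 lower, these 4 among them (edgeR adjusted p = 0.00195 to 0.0179). The covered-length offset turned 8 of the 10 RNAPII regions taken by smallest p.

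No RNAPII S5p region passed in edgeR (364 at an unadjusted p under 0.05, 14 higher and 1 lower by DESeq2). The smallest p stood at chr18:21042401-21065400 (log2 difference 2.01 ± 0.13 SE, edgeR adjusted p = 0.188; 168 and 232 reads in siCon, 1143 and 731 in siZC3H4), chrX:106880001-106903400 (1.61 ± 0.13, adjusted p = 0.309) and chr17:8374801-8399600 (2.00 ± 0.19, adjusted p = 0.396), all of which overlapped H3K36me3, as did 5199 of the 8176 S5p regions. Replicate 1 of both conditions again came from a run of its own. With the replicate block 0 passed in edgeR as well (666 at an unadjusted p under 0.05, DESeq2 without a block as above). Without siCon replicate 2, 181 were higher, and the covered-length offset turned 7 of the 10 S5p regions taken by smallest p.

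No RNAPII S2p region passed in edgeR (1368 at an unadjusted p under 0.05, 204 higher and 115 lower by DESeq2). The 10 regions taken by smallest p included chr1:2152001-2212200 (log2 difference -2.01 ± 0.15 SE, edgeR adjusted p = 0.134; 2424 and 2595 reads in siCon, 724 and 648 in siZC3H4), chr6:16644201-16696000 (-1.81 ± 0.21, adjusted p = 0.172), chr20:35460401-35493200 (-1.93 ± 0.22, adjusted p = 0.172) and, higher, chr22:31072801-31092600 (2.55 ± 0.26, adjusted p = 0.172; 103 and 121 against 746 and 695 reads). The covered-length offset turned 7 of these 10, among them chr1:2152001 (0.179), chr6:16644201 (0.403) and chr22:31072801 (-0.435). Of 13102 regions, scaling by library size alone called 345 higher and 92 lower. Without siZC3H4 replicate 2 there were 189 higher and 757 lower, and without siZC3H4 replicate 1, which came from another run than the other 3 libraries, 4 and 14; without siCon replicate 1 there were 5 and 1, and without siCon replicate 2 there were 2 and 0.

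No H3K36me3 region passed in edgeR without the replicate block (1647 at an unadjusted p under 0.05, 253 higher and 187 lower by DESeq2). At the regions taken by smallest p, read counts in siZC3H4 cells were higher at chr12:1734801-1762000 (log2 difference 2.93 ± 0.15 SE, edgeR adjusted p = 0.103; 187 and 174 reads in siCon, 1604 and 1313 in siZC3H4), chr20:25611001-25644600 (2.44 ± 0.14) and chr2:70235201-70313600 (1.08 ± 0.07), and lower at chr6:10963201-10981000 (-2.78 ± 0.17), each at the same adjusted p. The covered-length offset turned 2 of the 10 regions taken by smallest p. The replicate number matched the sequencing lane in both conditions, and with it as a block 776 of 12667 regions were higher and 520 lower, these 4 at edgeR adjusted p = 0.00138 to 0.00164. Without siCon replicate 1 the counts were 185 and 17, and without siCon replicate 2 65 and 11.

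The third question was which regions appeared or disappeared as calls. RNAPII S2p was called in both siCon and neither siZC3H4 library at 2686 regions, and the reverse at 410. The imbalance was much smaller without siZC3H4 replicate 1, the library from another run: 3087 regions were gained and 3590 lost, against 2077 and 8772 without siZC3H4 replicate 2, 770 and 6341 without siCon replicate 1, and 738 and 6702 without siCon replicate 2. The largest losses by read number included chr19:34744001-34793000 (2473 and 2192 reads in siCon) and chr10:88557401-88634000 (2721 and 1829). H3K36me3 of siCon cells overlapped 39.1% of lost S2p regions, much as it did gained ones (39.3%), and 74.3% of those called in all 4 libraries. SPT5 was lost at 1645 regions, among them chr19:34913201-34974600 (3189 and 1647 reads in siCon), and gained at 1370, among them chr7:82481801-82502200 (433 and 449 reads in siZC3H4). H3K4me3 was lost at 1313 peaks and gained at 601, and siCon RNAPII lay at 36.3% of the lost and 59.1% of the gained ones, against 79.6% of those called in all 4 libraries. The typical call was weak, with a median pileup per library of 20.0 in lost and 19.5 in gained peaks, against 210.75 in those called in all 4. Likewise, median reads per library were 78.5 in lost S2p regions (365.5 in all 4), and 76 in lost and 100.5 in gained SPT5 regions (193.5). H3K36me3 was gained at 1056 regions, led by chr19:44759801-44779400 (1858 and 1761 reads in siZC3H4), and lost at 591, led by chr18:71916001-71959200 (1973 and 1921 reads in siCon).

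For H3K27me3, 1315 regions were gained, 4 of the 5 with the most reads on the X chromosome (chrX:67296401-67344800, 2075 and 1970 reads), and 1133 were lost. X regions led the lost list too, with chrX:133490201-133582400 (935 and 3404 reads in siCon) and chrX:119386401-119430200 (2235 and 1501). RNAPII had 57 gained and 231 lost regions, with the ZC3H4-bound chr1:41461601-41507600 first among the gained (439 and 1681 reads) and chr19:36024401-36044000 first among the lost (1331 and 1923). RNAPII S5p had 501 gained and 130 lost. Only 3 ways to split 4 libraries into 2 pairs exist, so no p under 0.05 can be had from them. The condition split exceeded both other splits for S2p (3096 regions against 1446 and 1004), SPT5 (3015 against 1158 and 695), H3K4me3 (1914 against 796 and 480), H3K36me3 (1647 against 573 and 355) and H3K27me3 (2448 against 2142 and 1285), whereas the split by replicate number was larger for RNAPII (3822 against 288) and S5p (6521 against 631). Leaving out a library loosens the calls on 1 side, and which of gained and lost was larger turned in RNAPII without siCon replicate 2 (1382 gained, 572 lost) or siZC3H4 replicate 1 (2304, 329), in S5p without siCon replicate 1 (552, 4418), in SPT5 without siZC3H4 replicate 1 (7685, 3318) or 2 (4573, 2068), in H3K36me3 without siCon replicate 1 (1736, 1917), in H3K27me3 without siCon replicate 1 (3347, 3741) or 2 (2570, 4292) and in H3K4me3 without siZC3H4 replicate 1 (2049, 1960) or 2 (2573, 1865). Each siZC3H4 library was called against another input library than its siCon counterpart, so the input and the siRNA cannot be told apart in these calls.

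**Figure D4:**
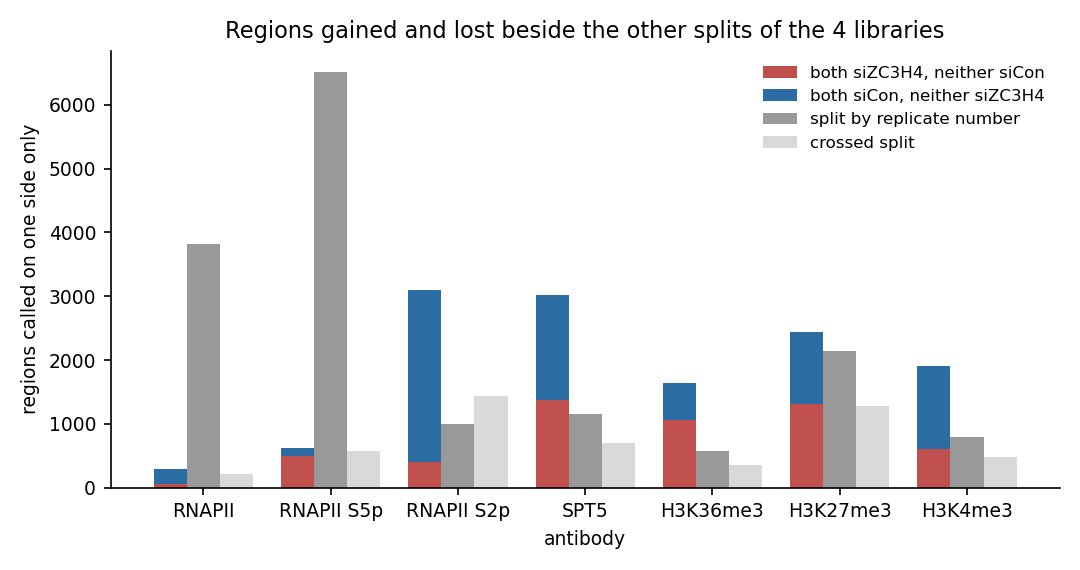
Regions called in both libraries of one side and neither of the other (vertical axis, count) for each antibody, with the gained (red) and lost (blue) regions of the condition split beside the split by replicate number (dark grey) and the crossed split (light grey). The condition split is the largest of the 3 for SPT5 (3015) and RNAPII S2p (3096) but not for RNAPII (288).

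SPT5 regions that were gained lay outside the active chromatin of siCon cells more often than those lost. H3K4me3 overlapped 3.5% of gained and 33.0% of lost SPT5 regions, RNAPII 2.4% and 25.8%, and H3K36me3 14.4% and 52.2% (Fisher's exact test, adjusted p = 8.91e-106, 1.65e-83 and 3.08e-109 over 5 region sets). H3K27me3 overlapped 21.6% of the gained and 1.3% of the lost (adjusted p = 1.57e-82), and ZC3H4 0.9% and 1.3% (adjusted p = 0.394). The gained regions were concentrated on a few chromosomes: chromosome 18 held 194 (2.49 per Mb), 7 held 269 (1.69), 6 held 238 (1.39), 10 held 142 (1.05) and 5 held 188 (1.04), while chromosomes 8, 11, 13 and X held 3, 8, 1 and 5. Neighbouring regions are not independent, so these p values are too small, and this comparison was not planned before the data were examined. The H3K4me3, RNAPII, H3K36me3 and H3K27me3 regions were those of siCon cells, in which the lost regions were called. A place active only in siZC3H4 cells would thus count as outside active chromatin. The siCon SPT5 libraries also shared their input with the siCon H3K36me3 libraries.

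**Figure D5:**
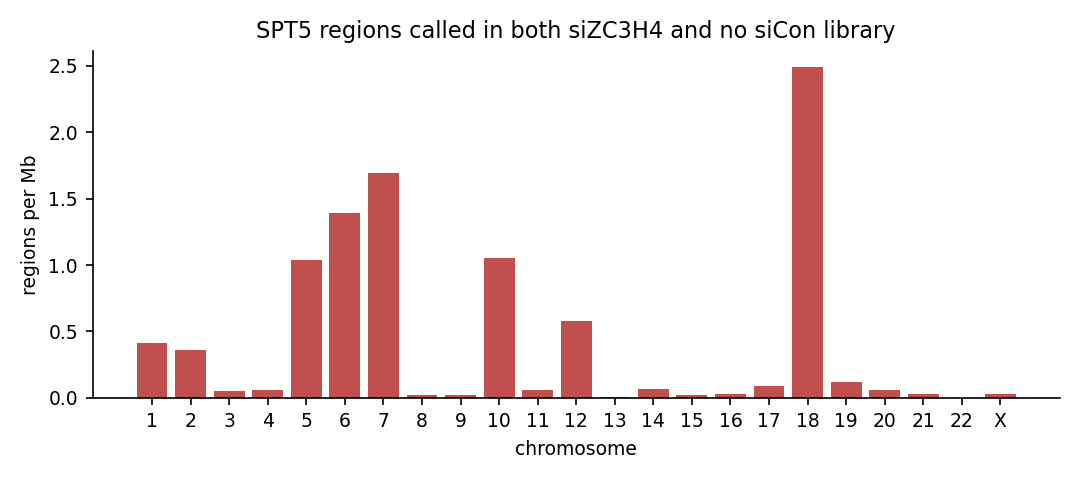
SPT5 regions called in both siZC3H4 and neither siCon library, per Mb of each chromosome (vertical axis). Chromosome 18 has 2.49 per Mb and chromosome 8 has 0.02.

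The fourth question was whether the sites that ZC3H4 occupies in untreated cells changed differently from other regions. They did not pass for any of the 7 antibodies. The median log2 difference of ZC3H4-bound regions minus that of the rest was -0.008 for RNAPII (1178 bound regions), 0.018 for S5p (899), 0.023 for S2p (1098), -0.010 for SPT5 (1201), 0.044 for H3K36me3 (936), 0.071 for H3K27me3 (29) and 0.012 for H3K4me3 (1551). Adjusted p from camera in limma, with a preset correlation of 0.01, lay between 0.469 and 0.715, and was 0.871 for all 7 with an estimated correlation. The smallest over all alternatives was 0.137, for H3K36me3 without siZC3H4 replicate 2.

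The last question was whether islands at promoters widened or narrowed. RNAPII S2p islands at H3K4me3 peaks were wider in both siZC3H4 libraries (6.70 and 6.32 kb, geometric means over 11414 regions) than in the siCon libraries (6.09 and 5.47 kb), a log2 difference of 0.174. SPT5 islands were 3.6 and 2.97 kb against 3.83 and 3.57 kb (-0.179). The differences were 0.135 for RNAPII, 0.193 for S5p, -0.233 for H3K4me3 and -0.021 for H3K36me3, and 51.2 to 58.7% of H3K36me3 widths and 23.6 to 28.9% of S2p widths per library reached the upper limit set on width. The exact two-sided permutation p was 0.333 for S2p, the smallest that 2 against 2 libraries allow, 0.667 for RNAPII, S5p, SPT5 and H3K4me3, and 1.000 for H3K36me3. Within same-numbered pairs 1 and 2 the sign was shared for H3K4me3 (-0.222 and -0.243, where replicates differed more than conditions), SPT5 (-0.09 and -0.269) and S2p (0.138 and 0.211), but not for RNAPII (0.304 and -0.034), S5p (0.577 and -0.192) or H3K36me3 (-0.096 and 0.054), and no paired test was run. Leaving out siCon replicate 1, siCon replicate 2, siZC3H4 replicate 1 and siZC3H4 replicate 2 in turn gave 0.254, 0.098, 0.136 and 0.212 for S2p, -0.13, -0.228, -0.324 and -0.044 for SPT5, 0.009, 0.268, 0.095 and 0.171 for RNAPII, -0.033, 0.428, 0.042 and 0.341 for S5p, -0.428, -0.037, -0.035 and -0.412 for H3K4me3, and 0.038, -0.077, -0.006 and -0.045 for H3K36me3. Widths follow depth as well as occupancy, and they do not separate the upstream from the downstream side of a promoter. They are those of the first overlapping island only, so a region broken into pieces counts as narrow.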

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

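Of the tests in this part, those on sequencing run and input, on scaling with pileup height, on ZC3H4 sites and on chromosome copies were chosen only after the result was seen. The bound for low depth was written before, but reading it with an interval and with the reverse overlap was chosen after, as was reading the ZC3H4 sites also with cyclic loess and the sum of pileups. The mitochondrial genome, on which the report gives no result, gave an island above its input in 17 of the 34 island libraries. These held 25342 to 30811 reads at 3.5 to 19.06 times the input, and the read number was 77.3 to 93.9% of the strand positions in the island. All 17 libraries also had an island in the same 7 kb near the start of chromosome 1, and 0 of the other 17 did.

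The 2 ZC3H4 libraries of untreated cells shared few regions, with a Jaccard index of 0.049 between their islands. Low depth or weak enrichment is not decided: of the densest 10% of replicate 1 islands 22.5% overlapped an island of replicate 2 (upper 95% limit 25.0%), near the bound of 25% set against it, whereas the reverse overlap was 55.3%. Among the 6 ZC3H4, WDR82 and CK2a libraries, all 6 shared the most sequence with another of these antibodies from the same run and input when only these are compared. When all untreated libraries are compared, 5 of the 6 were closest to any other antibody of the same run. CK2a replicate 1 was then closest to RNAPII of its run, and WDR82 replicate 1 to H3K4me3, of another run. A contribution of run or input to the islands would give this pattern. A biological difference between replicates was not tested. The regions called in both replicates come from 2 runs and 2 inputs, and 92.8% of them lay at RNAPII.

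H3K4me3 fell more often at peaks without RNAPII. Scaling that depends on pileup height is argued against as the whole cause: the log2 difference between peaks with and without RNAPII was 0.131 (0.093 and 0.163 in the same-numbered pairs) and at matched pileup 0.087 (0.096 and 0.071), so pileup height can account for part of it. Differences between single libraries are argued against, since the larger replicate difference was 0.019 in size. Loss of ZC3H4 at the sites it occupied is not decided, with 7.6% of the lower calls at ZC3H4 regions against 8.5% of regions not called (9.1% against 8.5% with cyclic loess, 5.7% against 8.4% with the sum of pileups), and few ZC3H4 regions lie at peaks without RNAPII. An indirect effect of the siRNA may explain the pattern, as a hypothesis from the same data. The different inputs of the 2 conditions remain open, as does the width of the regions, which was not matched.

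SPT5 islands were gained away from the H3K4me3 peaks of siCon cells, on a few chromosomes. Over chromosomes, the ratio of gained to lost regions followed the ratio of regions found in siZC3H4 replicate 2 only to replicate 1 only (Spearman's rho 0.68), which is consistent with a library bias along chromosomes. The gained regions overlapped islands of the untreated ZC3H4 replicate 2, another antibody without siRNA, 5.64 times as often as random placements (lost regions 1.59 times), so places that give islands with many antibodies may contribute. Input density here was the median of input reads per kb inside the H3K27me3 islands of siCon replicate 1, relative to all of these islands. It came from another input than those of the SPT5 libraries, so it stands in for copy number only roughly. As far as it does, more copies of some chromosomes are argued against as the whole cause. Of the 11 chromosomes with high input density (at least 1.1 times the median), 4 had more gained regions per Mb than the 0.47 of all chromosomes together. Chromosome 22 had 0 gained regions at an input density of 1.17 times the median, and chromosome 7 had 269 at 1.05. Gained regions per Mb still followed input density with a rho of 0.43 over 23 chromosomes, so copies may contribute. A gain of SPT5 outside the active chromatin of siCon cells after loss of ZC3H4 stays open.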

How the results depend on the processing

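The scaling to whole-library depth was chosen only after the data were seen, and the other alternatives were planned. Over all comparisons, 250 values kept their direction and side of the threshold or, for counts and widths, lay within 1.5 times the count or within 1 SD of replicates, 151 moved further and 9 reversed. Such values can still differ in size or, where no test passed, in sign. Of the values of single regions or splits of calls, 244 kept their direction and side, 49 also passed the threshold, 33 no longer passed and 12 reversed. Where a value below differs, the cause was not tested unless it is named.

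In untreated cells, every overlap of ZC3H4 except that with H3K27me3 stayed above random placements, but with a single ZC3H4 replicate they were smaller: RNAPII from 92.82 to 66.05 or 37.93%, H3K4me3 from 90.52 to 56.97 or 35.78%, SPT5 from 87.8 to 56.5 or 35.03%, WDR82 from 73.94 to 39.99 or 25.2% and CK2a from 64.75 to 29.83 or 23.46%. H3K27me3 ranged from 0.8 to 18.72% and reversed with replicate 2 alone.

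DESeq2 called more island regions than edgeR, higher and lower: RNAPII 5 and 4, S5p 14 and 1, S2p 204 and 115, SPT5 27 and 58, H3K36me3 253 and 187, H3K27me3 16 and 18. Library size alone gave RNAPII 1 lower, S2p 345 and 92, SPT5 5 and 21, H3K36me3 14 and 5. Regions called in at least 2 libraries gave 0 and 0 in edgeR for SPT5 (3746 at an unadjusted p under 0.05) and 0 higher for H3K27me3 (3112). The covered-length offset gave SPT5 7 higher and 0 lower and H3K27me3 1 higher, which was neither of the 2 H3K27me3 regions called without it. The replicate block gave RNAPII 13 and 5, SPT5 17 and 45, H3K36me3 776 and 520, and H3K4me3 881 and 1660.

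Whole-library depth gave SPT5 9 higher and 363 lower and H3K27me3 1 higher. It put the median of all regions at -0.499 for SPT5, -0.321 for S2p and 0.11 for S5p on the log2 scale, and library size alone put S5p at -0.265 and S2p at 0.175. Changes in the report are relative to these medians.

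The covered-length offset turned the sign of 42 of the 63 island regions taken by the rule (RNAPII 8 of 10, S5p 7, S2p 7, SPT5 11 of 13, H3K36me3 2, H3K27me3 7). By its construction it removes what island length adds to a count. Of the regions named in the report it turned these. RNAPII: chr19:11428401 from -1.779 to 0.412, chr10:75552401 from 1.192 to -1.181, chr22:42321201 from -1.074 to 0.742. S5p: chr18:21042401 from 2.013 to -0.103, chr17:8374801 from 1.995 to -0.111. S2p: chr1:2152001 from -2.01 to 0.179, chr22:31072801 from 2.545 to -0.435, chr6:16644201 from -1.808 to 0.403. SPT5: chr7:82553801 from 3.085 to -0.367, chr10:27019601 from -2.499 to 0.195, chr15:89848601 from -2.261 to 0.987, chr10:64913801 from -2.097 to 0.138.

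For H3K4me3, cyclic loess gave 776 higher, quantile normalization 744 higher, the fold enrichment 1344 and 1655, and the sum of pileups 258 and 53.

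Within same-numbered pairs more regions were gained and lost, because fewer libraries must share a call. Pair 1 gave, gained and lost, RNAPII 1909 and 1420, S5p 6644 and 1430, S2p 2995 and 15981, SPT5 5236 and 7325, H3K36me3 4440 and 1982, H3K27me3 5191 and 7225, H3K4me3 4840 and 5588. Pair 2 gave RNAPII 2384 and 5492, S5p 5763 and 5181, S2p 5267 and 7937, SPT5 8648 and 7071, H3K36me3 2499 and 2994, H3K27me3 8962 and 6573, H3K4me3 2709 and 6317. The log2 width differences of pairs 1 and 2 were 0.304 and -0.034 for RNAPII, 0.577 and -0.192 for S5p, and -0.096 and 0.054 for H3K36me3. Without siCon replicate 1 the width difference changed sign for S5p (0.193 to -0.033) and H3K36me3 (-0.021 to 0.038), and H3K4me3 (-0.233) ranged from -0.428 to -0.035 with 1 library left out.

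At ZC3H4-bound regions the difference reversed for H3K27me3 with ZC3H4 in either replicate (-0.022), and with a matched background for S5p (-0.018) and H3K4me3 (-0.002).

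With each library left out in turn, the lone library of a condition is assumed to vary like the others. Gained and lost ranges were RNAPII 70 to 2304 and 329 to 5070, S5p 552 to 5595 and 242 to 4418, S2p 738 to 3087 and 3590 to 8772, SPT5 1558 to 7685 and 2068 to 6501, H3K36me3 1629 to 3090 and 869 to 1917, H3K27me3 2570 to 4662 and 2585 to 4292, H3K4me3 884 to 2573 and 1865 to 4948. Higher and lower calls ranged for S5p from 0 to 181 higher, for S2p from 2 to 189 and 0 to 757, for SPT5 from 0 to 20 and 0 to 65, for H3K36me3 from 0 to 185 and 0 to 17, for H3K27me3 from 0 to 6 higher and for H3K4me3 from 217 to 397 and 395 to 786. At ZC3H4-bound regions the difference ranged from -0.033 to 0.016 for RNAPII, -0.02 to 0.047 for S5p, -0.009 to 0.052 for S2p, -0.036 to 0.001 for SPT5 and -0.031 to 0.098 for H3K27me3.

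The tests of gene lists with their alternatives and the distance of 10 kb to other genes were not run, because they need an annotation of the build used here. Simulated 2-fold changes were recovered at 12% for S2p and 27% for H3K27me3, so few calls there do not show few changes.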

Other observations

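Of the tests in this part, those of H3K27me3 and H3K4me3 at regions that hold the other mark and the whole-library scaling were chosen only after the data were seen. H3K27me3 regions that also held H3K4me3 in siCon cells had more H3K27me3 in siZC3H4 cells than other H3K27me3 regions. Their median log2 difference was 0.14 over 701 regions against -0.01 for the rest, with 0.11 and 0.18 more than the rest in the same-numbered pairs (camera in limma, adjusted p = 2.67e-10 over 50 sets, adjusted p = 0.332 with an estimated correlation). This difference was not examined at matched read counts. H3K4me3 had a median of -0.13 at 694 regions that held H3K27me3 against -0.03 at the rest (camera in limma, adjusted p = 0.0387, and 0.663 with an estimated correlation), but at matched pileup the difference shrank from -0.103 to -0.046 and was -0.087 and 0.01 in the 2 pairs. Among the 527 regions matched between the marks, 10 had an unadjusted p under 0.05 for both, and 1 of these had the same direction.

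Where 2 of RNAPII, S5p, S2p and SPT5 both had an unadjusted p under 0.05, they mostly shared their direction. RNAPII and SPT5 did so at 117 of 124 regions, RNAPII and S5p at 79 of 81, RNAPII and S2p at 57 of 62, S2p and SPT5 at 94 of 102, S5p and SPT5 at 42 of 47, and S5p and S2p at 36 of 37. With H3K36me3 the direction was shared at 15 of 30 regions for RNAPII, 17 of 24 for S5p, 104 of 118 for S2p and 30 of 43 for SPT5. With H3K4me3 it was shared at 127 of 148 for RNAPII, 44 of 55 for S5p, 75 of 117 for S2p and 116 of 150 for SPT5. The hypothesis that the siRNA changed regions in all these antibodies together was tested across regions with no library number in common. For 5 of the 6 antibody pairs of RNAPII, S5p, S2p and SPT5 the correlation was over 0.1 and over 2 times that of replicate differences from opposite conditions (RNAPII with SPT5 0.266 against 0.047), while RNAPII with S5p was not (0.248 against 0.293). RNAPII with S2p passed narrowly (0.203 against 0.099) and would not have passed against replicate differences of the same condition (0.137). Regions are not independent replicates. A shared input can also move islands of several antibodies together. RNAPII of replicate 1 and SPT5 of replicate 2, which had no input in common, gave 0.182, against 0.349 for the reverse, which shared both inputs. S5p of replicate 1 and SPT5 of replicate 2 likewise had no input in common and gave 0.109, against 0.306 for the reverse, which shared both. S2p of replicate 1 and SPT5 of replicate 2 shared the siCon input and gave 0.14, against 0.243 for the reverse, which shared both. Pairs with S2p differed: S5p of replicate 1 and S2p of replicate 2, without a common input, gave 0.257. The reverse, which shared the siCon input, gave 0.164. For RNAPII with S2p these values were 0.196 and 0.209. A shared input thus did not always go with a higher correlation.

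The whole-library scaling lowered most SPT5 regions. Under it 5% of SPT5 regions were above 0 in siZC3H4 against siCon cells, and the median log2 difference was -0.26 in pair 1 and -0.81 in pair 2. This scaling rests on 1 ratio of ChIP to input per library, and no spike-in was used here.

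Islands outside the RNAPII, S2p, H3K36me3 and H3K4me3 regions of siCon cells were unevenly spread over chromosomes in untreated cells too. ZC3H4 replicate 2 had 8.15 such islands per Mb on chromosome 18 and 0.06 on chromosome 8, and SPT5 replicate 1 had 2.81 and 0.01. The values were 10.31 and 0.01 for siZC3H4 SPT5 replicate 2, 5.41 and 0.02 for replicate 1, and 0.13 and 0.05 for siCon RNAPII replicate 1.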
